A study of Mus musculus with 6 samples.

How the data were processed

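RNA from the hearts of 6 C57BL/6 mice was measured on 1-colour Affymetrix arrays, with 1 array for each of 3 infected and 3 uninfected mice. RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. Groups were taken from the labels, and replicate numbers served only to name the arrays.

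The deposited value table holds 1 linear signal intensity per probe set and array, for 22690 probe sets. Every array has a 2% trimmed mean of 500.2, so the authors' values had been scaled to a common level before deposit. The submitters' processing notes name MAS5, RMA and affy without roles or versions. Values that are linear, above 0 and scaled to an equal trimmed mean are of the MAS5 kind, while the probe set annotation release and genome build are not given in the sources used here. MAS5 subtracts background estimates from the signals of probes, which makes the log of a dim signal noisy. No detection calls were used. The authors' deposited workbook holds, for 12343 probe sets, a fold change (ratio) of infected over uninfected hearts written as 1 or more with a direction, and its 2 shorter sheets hold the members of the first with a fold of at least 2. The titles of those sheets name significant genes and a p of 0.05, but the test behind them is not given in the sources used here.

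Gene names came from the workbook's first sheet. Of the 22626 probe sets that are not array controls, 11276 carried 1 gene symbol, 883 carried several and 11350 had no single name here, which includes those with several. Symbols were brought up to date with a RefSeq gene table of assembly GRCm38.p6: 9814 were current, 1265 were updated through a synonym and 197 were kept. This gave 8081 named genes, each represented by its probe set with the highest mean. The sheet covers 91.5% of the probe sets that rose in the fit, 87.4% of those that fell and 44.1% of those that passed no threshold, so changed genes are over-represented among the named ones, and counts of list members are counts of named members. Nos2, Cxcl10, Myh7 and Col1a1, which had been set down for reporting, are not named here. All 5 sex-linked genes are likewise not named here, so the sex of the mice was not checked.

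Signals were set to a floor at the 1st percentile of all values (a signal of 1.35, applied to 0.984% of values) and converted to log2. Infected was compared with control by limma (version 3.58.1, lmFit and eBayes, in R 4.3.3), with Benjamini-Hochberg adjustment over 22626 probe sets. A probe set, or the gene it stands for, is said to have risen, fallen or changed where its adjusted p was under 0.05. Errors of log2 fold changes are standard errors of the fit with n = 3 arrays per group, and group means of signals are geometric means. Other probe sets of a named gene were also examined. Among 61 of them, 1 had the opposite sign. Dhx58, Cpt1a, Dlst, Tnni2 and Cd4 had no other probe set past the threshold, and Ldb3, Tef and Gstm1 had some that passed it and some that did not, all of the same sign.

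Before the data were examined, 46 gene lists were fixed: interferon-gamma-inducible and type I interferon-stimulated genes, MHC class I and class II genes, chemokines, cytokines, cytotoxic, inhibitory receptor, phagocyte oxidase, complement, innate sensing and proliferation genes. Cell type lists covered T, B and plasma, natural killer, monocyte and macrophage, resident macrophage, neutrophil, dendritic, mast and eosinophil, endothelial, fibroblast and smooth muscle cells. Heart lists covered fatty acid oxidation, the tricarboxylic acid cycle, respiratory complexes, glycolysis, energy regulators, the sarcomere, ion handling, cell junctions, the cardiac stress program, matrix, cell death and redox genes. Check lists covered clock, glucocorticoid-responsive, immediate-early, ribosomal protein, erythroid, skeletal muscle, adipocyte, thymus and lung, atrial and sex-linked genes. The 43 lists with at least 5 named members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusting over the 43 lists. Camera compares a list with the other named genes, and fry asks only whether a list's own genes move one way. At the preset correlation, camera takes its degrees of freedom from the number of genes, so its p values do not reflect the few mice. At an estimated correlation it takes them from the arrays, so its p values differ for more than the correlation. In the inhibitory receptor list the estimated correlation was 0.02, yet camera's adjusted p moved from 3.9e-07 to 0.14.

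The rule for naming genes was fixed at the same time. It takes, among changed genes whose groups do not overlap, the 8 with the highest and the 8 with the lowest log2 fold change, then the leading changed members of each list, ordered by log2 fold change before any floor at 64, with the largest opposite one, the leading member as values where none changed, and a fixed set of immune and heart genes. Some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen. For each array, the mean log2 signal of the energy metabolism lists minus that of the sarcomere list was compared between groups by a two-sided exact permutation test with scipy 1.17.1, which cannot give a p below 0.1 with 3 against 3 arrays.

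The limma fit was tested on simulated data of 22626 probe sets with the measured means and spreads. The simulated changes lay only in probe sets above the median brightness, and noise was drawn independently for each probe set. The fit called 49% of 2-fold and 92% of 4-fold changes with no wrong sign, and 10 of its 160 calls were unchanged probe sets. These rates do not cover changes in dim probe sets or data in which far more probe sets change. The spread between arrays depends on brightness. The median SD was 0.72 log2 units for 7270 probe sets with a mean signal under 64, 0.24 for 9572 between 64 and 512 and 0.14 for 5784 above 512. At these spreads the 95% interval of a difference between groups reaches about 1.62, 0.54 and 0.31 log2 units to either side. Where a group's mean signal lay under 64, folds in the text are computed with signals under 64 set to 64 and written as "at least", a choice made after the data were seen. The wording "at least" marks that scale and is not a statistical lower bound. The number of arrays limits the precision of every value.

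Alternatives covered 3 other scalings, 2 filters on dim probe sets, other variance models, array weights, the replicate number as a block, leaving out each array, a stricter threshold, other choices of probe set and other list tests. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used for the tables.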

Results

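Hearts of C57BL/6 mice, an inbred laboratory strain, were compared 18 days after infection with the Y strain of Trypanosoma cruzi, the protozoan parasite of Chagas disease, and without infection. Each group held 3 mice with 1 array each, and the design text asks how gene expression differs between the 2 groups. Signals of 22690 probe sets were read on every array. The arrays had the same trimmed mean, and their median signals ran from 157.9 to 170.8. Across probe sets, which are not independent, log2 signals correlated with r between 0.968 and 0.979 among infected hearts, between 0.974 and 0.981 among controls, and between 0.823 and 0.846 across the groups.

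Infected hearts gave higher signals than control hearts for interferon-induced, T cell, cytotoxic, macrophage and proliferation genes, and lower signals for fat cell and heart muscle metabolism genes. The 8 genes with the highest log2 fold changes of those that passed the threshold had mean signals under 64 in controls, which leaves their order uncertain. They were Acod1, which makes itaconate in activated macrophages (mean signal 998 against 3.08, at least 15.6-fold), the granzyme gene Gzma (at least 79.2-fold), the cytokine gene Ifng (576 against 2.2, at least 9.0-fold, adjusted p = 0.00012), the guanylate-binding protein gene Gbp8 (at least 20.6-fold), Gzmb (at least 98.8-fold), the lectin receptor gene Klrc1 (at least 4.42-fold), Cd3d of the T cell receptor complex (at least 16.8-fold) and arginase, Arg1 (at least 6.65-fold). Among the 8 genes with the lowest log2 fold changes of those that passed the threshold were the macrophage scavenger receptor gene Cd163 (2.04 against 205, at least 3.2-fold lower), carbonic anhydrase 3, Car3 (160 against 8028, 50.3-fold lower), and the fat cell hormone gene Adipoq (at least 21.4-fold lower). The infected signals of Car3 were 31.5, 366 and 353, so 1 array weighs on the size of its fold.

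Pck1, Cidec, Scd1, Pon1 and Gnmt completed these 8. Scd1, a fatty acid desaturase gene, was 14.6-fold lower (306 against 4480, adjusted p = 0.015). Its control signals were 3156, 2282 and 12485, so control replicate 3 weighs on the size of the fold. Mean signals of the other 4 genes were under 10 in infected hearts and between 76.2 and 235 in controls. With signals under 64 set to 64, Pon1 was at least 1.57-fold lower (adjusted p = 0.028), while the adjusted p became 0.21 for Pck1, 0.35 for Cidec and 0.37 for Gnmt.

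Of 22626 probe sets tested with limma, 2401 rose and 2766 fell, and 1525 rose and 860 fell by at least 2-fold. Among 8081 named genes, 1407 rose and 1607 fell. In each of the 5167 probe sets that changed, the 3 infected arrays lay on one side of the 3 controls, as they did in 45.1% of all probe sets, where chance gives 10%. The median log2 fold change was -0.16 over all probe sets and -0.23 over named genes. Leaving out any array but infected replicate 1 lowered at least 1 of these counts by over 1.5 times. Without infected replicate 2, infected replicate 3, control replicate 1, control replicate 2 and control replicate 3 in turn, 1510, 1465, 1852, 1567 and 1598 probe sets rose and 1542, 1299, 1412, 1272 and 1219 fell. In the same order, 916, 860, 1096, 938 and 945 genes rose and 876, 762, 826, 729 and 717 fell. In the gene lists that follow, counts cover named members, and the sheet that supplied the names covered 91.5% of probe sets that rose, 87.4% of those that fell and 44.1% of the rest, which raises the share of members that changed.

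**Figure D1:**
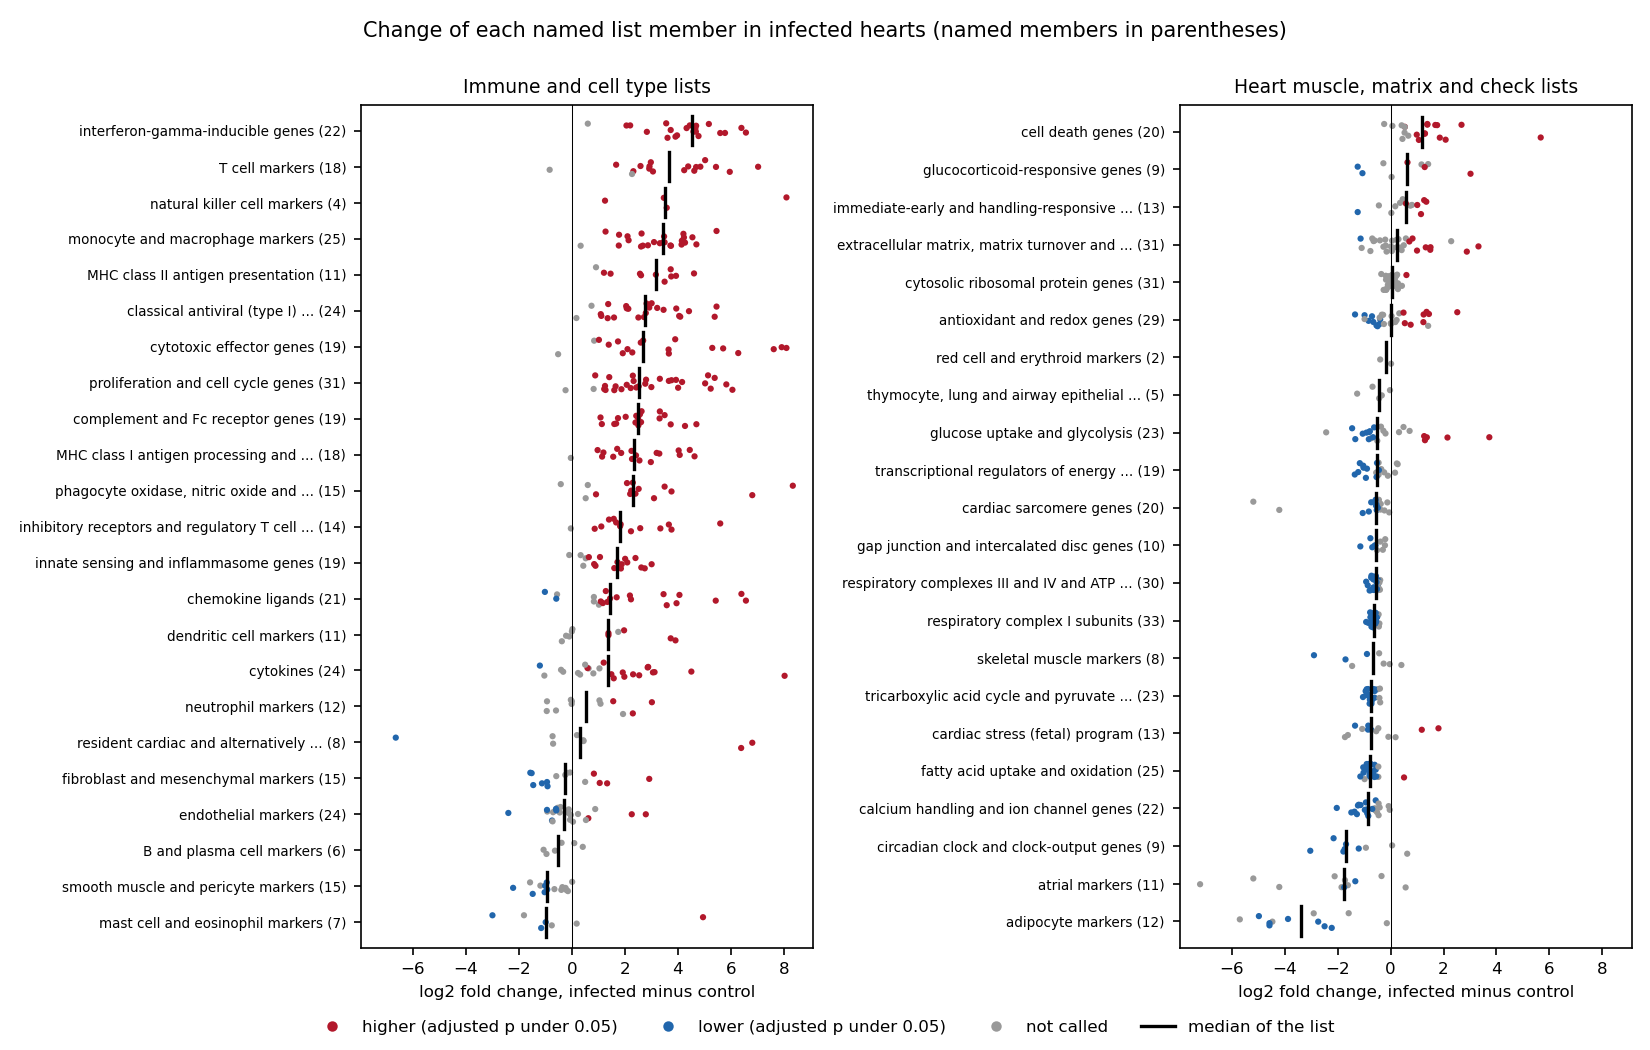
Log2 fold change (x axis, infected minus control, 3 arrays per group) of each named member of the gene lists, 1 row per list, with red for members that rose, blue for members that fell, grey for the rest and a black bar at the list's median. Medians run from 4.52 for interferon-gamma-inducible genes to -3.39 for adipocyte markers.

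List medians count dim members at their own signals. With signals under 64 set to 64, the median became 2.55 for T cell markers, 2.14 for cytotoxic, 1.45 for proliferation and 0.79 for cytokine genes, 0.1 for matrix genes, 0.0 for B and plasma cell markers, -0.4 for smooth muscle and pericyte markers and -2.36 for adipocyte markers.

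Genes induced by interferon rose almost without exception. Of 22 named interferon-gamma-inducible genes, 21 rose (22 adjusted over the list alone), with a median log2 fold change of 4.52 (camera adjusted p = 3.9e-17, and adjusted p = 0.14 with an estimated correlation). Gbp6, a guanylate-binding protein gene, was 94.9-fold higher (log2 fold change 6.57 ± 0.23), the T cell attracting chemokine gene Cxcl9 84.7-fold higher (6.40 ± 0.22) and the immunity-related GTPase gene Irgm1 25.9-fold higher (4.69 ± 0.21). Of 24 classical type I interferon-stimulated genes, 22 rose (23 adjusted over the list alone), with a median of 2.76 (adjusted p = 1.2e-13, and adjusted p = 0.14 with an estimated correlation). The RNA sensor gene Dhx58 was at least 4.6-fold higher, Ifit2 42.0-fold higher and Ifit3 21.4-fold higher.

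Antigen presentation genes rose alongside. In MHC class I processing and presentation, 17 of 18 named genes rose (17 adjusted over the list alone, median 2.34, adjusted p = 1.5e-11, and adjusted p = 0.14 with an estimated correlation), led by the immunoproteasome subunit genes Psmb8 (24.8-fold) and Psmb9 (21.8-fold) and the peptide transporter gene Tap1 (16.8-fold). In MHC class II presentation, 10 of 11 rose (10 adjusted over the list alone, median 3.17, adjusted p = 2.6e-07, and adjusted p = 0.24 with an estimated correlation). H2-DMb1, which encodes a chain of the peptide-exchange protein, was at least 11.7-fold higher and H2-DMa 15.2-fold higher.

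Most named chemokine and cytokine genes rose. Of 21 named chemokine genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, median 1.44, adjusted p = 5.8e-07, and adjusted p = 0.14 with an estimated correlation). Ccl5 was 94.9-fold higher (6.57 ± 0.18, adjusted p = 0.00025) and Ccl3 at least 4.1-fold higher. Cxcl14 fell (-1.02 ± 0.26), from a mean signal of 92.6 to 45.6, a call that ended with signals under 64 set to 64 (adjusted p = 0.17). Of 24 named cytokine genes, 14 rose and 1 fell (17 and 2 adjusted over the list alone, median 1.35, adjusted p = 1.7e-06, and adjusted p = 0.14 with an estimated correlation). With Ifng, Ltb (at least 13.2-fold) and Il6 (at least 2.38-fold) rose, while Tgfb3 was 2.31-fold lower. The cytokine list's call ended among probe sets above the median brightness (median 0.54, adjusted p = 0.059). Tnf was at least 2.82-fold higher. Il10, which encodes an inhibitory cytokine, rose from a mean signal of 26.9 to 80.4 (1.58 ± 0.26, adjusted p = 0.013), with an adjusted p of 0.12 once signals under 64 were set to 64.

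Most cytotoxic and T cell genes rose. All 19 cytotoxic effector genes were named and 17 rose (17 adjusted over the list alone, median 2.69, adjusted p = 2.8e-10, and adjusted p = 0.14 with an estimated correlation), among them Gzma and Gzmb. Of 18 T cell markers, 16 rose (17 adjusted over the list alone, median 3.65, adjusted p = 6.6e-10, and adjusted p = 0.14 with an estimated correlation), among them Cd3d and the adaptor gene Lat (at least 12.4-fold). The coreceptor gene Cd8a rose from 63.1 to 1196 (at least 17.1-fold, adjusted p = 0.00069). Cd4 reached a mean signal of only 92.6, from 11.7 (2.98 ± 0.63, adjusted p = 0.025), and its adjusted p was 0.33 with signals under 64 set to 64. In the list of inhibitory receptor and regulatory T cell genes, 13 of 14 rose (13 adjusted over the list alone, median 1.83, adjusted p = 3.9e-07, and adjusted p = 0.14 with an estimated correlation). Its members Foxp3, Ctla4, Il2ra and Tigit are not named here, and Ikzf2 was the member that did not rise (-0.04). The count therefore does not show a rise of regulatory T cells. Among the members that rose, the checkpoint ligand gene Cd274 was 48.4-fold higher and Lag3 at least 3.23-fold higher.

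All 4 named natural killer cell markers rose (4 adjusted over the list alone, too few for a list test), among them Gzma and Xcl1. The means of Xcl1, 53.1 and 4.45, both lay under a signal of 64, and its adjusted p was 0.58 with lower signals set to 64. Ncr1, Klrb1c and the Klra genes of this list are not named here. The named markers do not set natural killer cells apart from cytotoxic T cells. No B or plasma cell marker among 6 named ones changed (0 adjusted over the list alone, median -0.52, camera adjusted p = 0.94). Sdc1 had the largest value of that list (-1.07 ± 0.51, adjusted p = 0.19), and a second probe set of the gene fell (-1.39, adjusted p = 0.0066).

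Of 25 monocyte and macrophage markers, 24 rose (24 adjusted over the list alone, median 3.44, adjusted p = 2.5e-14, and adjusted p = 0.22 with an estimated correlation). The pore-forming protein gene Mpeg1 rose by 5.46 ± 0.52 on the log2 scale. The Fc receptor gene Fcgr4 was 26.0-fold higher and the pan-leukocyte gene Ptprc 19.3-fold higher (4.27 ± 0.44, adjusted p = 0.0036). Complement and Fc receptor genes rose in 19 of 19 cases (19 adjusted over the list alone, median 2.51, adjusted p = 3e-12, and adjusted p = 0.14 with an estimated correlation), with Fcgr4 ahead of complement factor B, Cfb (19.4-fold). Phagocyte oxidase, nitric oxide and arginine genes rose in 12 of 15 cases (13 adjusted over the list alone, median 2.3, adjusted p = 1.4e-07, and adjusted p = 0.14 with an estimated correlation), among them Acod1 and Arg1. Innate sensing genes rose in 15 of 19 cases (15 adjusted over the list alone, median 1.72, adjusted p = 4.7e-08, and adjusted p = 0.14 with an estimated correlation), among them the lectin receptor gene Clec4e (at least 2.62-fold, with a second probe set at 0.42, adjusted p = 0.17) and the Toll-like receptor gene Tlr1 (at least 4.92-fold).

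Markers of resident and alternatively activated macrophages went both ways. Of 8 named ones, 2 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.31, camera adjusted p = 0.33, and fry higher with adjusted p = 0.043). Arg1 and the chitinase-like gene Chil3 (at least 6.0-fold) rose, and Cd163 fell. Folr2, Mrc1 and Stab1, chosen after their values were seen, had log2 fold changes of 0.43 ± 0.12, 0.19 ± 0.26 and 0.44 ± 0.16 (adjusted p = 0.059, 0.63 and 0.11).

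Neutrophil markers rose in 3 of 12 cases (3 rose and 1 fell adjusted over the list alone, median 0.52, camera adjusted p = 0.11, and fry higher with adjusted p = 0.021). Camera called the list among probe sets above the median brightness (adjusted p = 0.014) and without control replicate 2 (adjusted p = 0.023). Lcn2, which several cell types express, was 8.09-fold higher and the formyl peptide receptor gene Fpr2 4.92-fold higher. The calgranulin genes S100a8 and S100a9, chosen after their values were seen, stood at 1.93 ± 0.72 and 1.08 ± 0.73 (adjusted p = 0.11 and 0.33). Dendritic cell markers rose in 5 of 11 cases (5 adjusted over the list alone, median 1.38, adjusted p = 0.022, and adjusted p = 0.39 with an estimated correlation), led by the transcription factor gene Irf8 (15.1-fold) and the integrin gene Itgax (13.3-fold), both of which macrophages also express. The list's call ended with signals under 64 set to 64, where its median was 0.02 (adjusted p = 0.058).

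Proliferation genes rose in 29 of 31 cases (30 adjusted over the list alone, median 2.52, adjusted p = 2.5e-14, and adjusted p = 0.14 with an estimated correlation). Mki67, a marker of cycling cells, was at least 11.6-fold higher and the ubiquitin-conjugating enzyme gene Ube2c at least 7.95-fold higher. Cell death genes rose in 13 of 20 cases and none fell (15 rose adjusted over the list alone, median 1.18, adjusted p = 1.2e-07, and adjusted p = 0.14 with an estimated correlation). The BH3-only genes Pmaip1 and Bid were at least 2.31-fold and at least 3.85-fold higher, and a second probe set of Bid pointed the other way without passing the test (-0.29, adjusted p = 0.35).

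**Figure D2:**
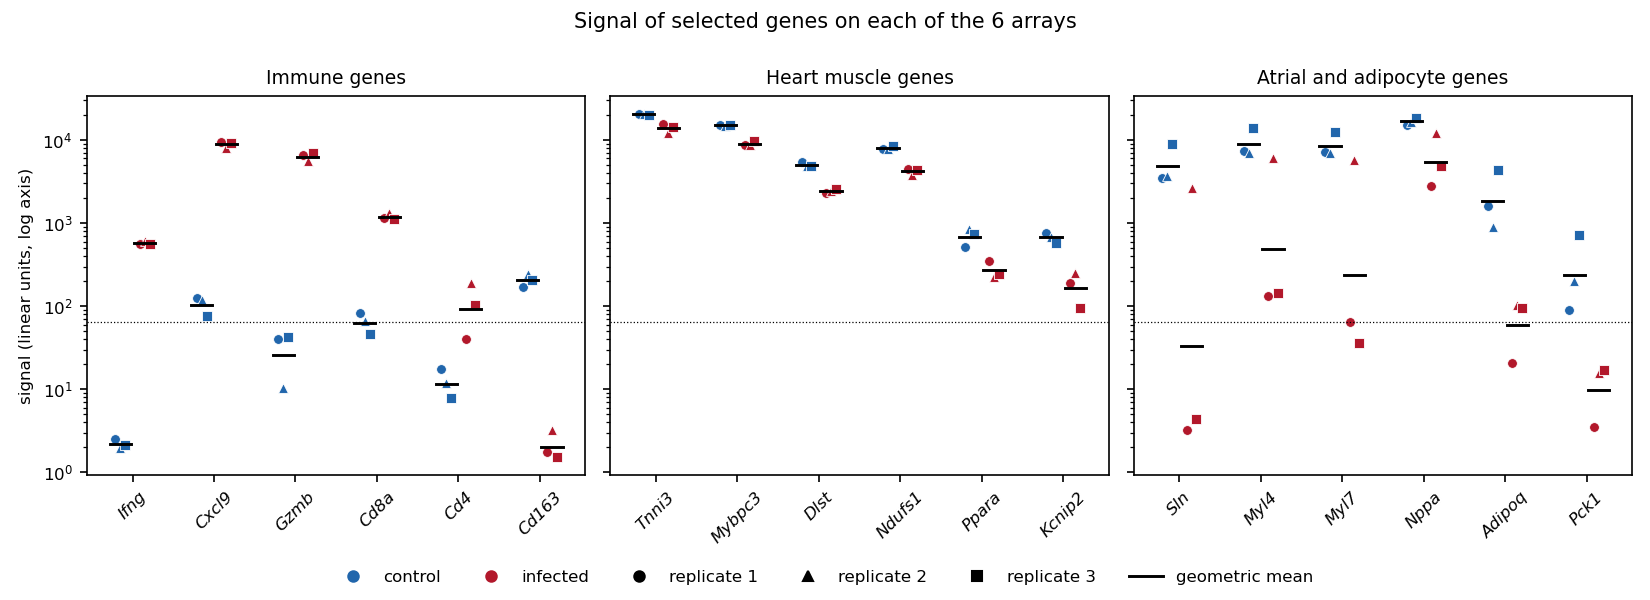
Signal (y axis, linear units on a log axis) of 18 genes on each array, with control hearts in blue, infected hearts in red, a symbol for each replicate number, black bars at geometric means and a dotted line at a signal of 64. Ifng and Cd163 part the groups completely, while Sln, Myl4 and Myl7 lie near control level on infected replicate 2 and far below it on infected replicates 1 and 3.

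Genes of mitochondrial energy metabolism, which dominate the heart muscle cell, fell together, with list medians between -0.77 and -0.56 on the log2 scale. Under quantile normalization the medians, in the order of the lists below, were -0.61, -0.56, -0.45 and -0.29, and all 4 calls stayed (highest adjusted p = 0.0014). Of 25 fatty acid uptake and oxidation genes, 21 fell and 1 rose (24 and 1 adjusted over the list alone, median -0.77, or 1.7-fold lower, adjusted p = 5e-06, and adjusted p = 0.3 with an estimated correlation). The carnitine acetyltransferase gene Crat was 2.2-fold lower (-1.14 ± 0.12, with a second probe set at -0.55, adjusted p = 0.26) and Acads 2.04-fold lower, whereas Cpt1a, the form of carnitine palmitoyltransferase abundant in liver and other non-muscle tissues, was 1.42-fold higher. Of 23 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 19 fell (22 adjusted over the list alone, median -0.72, adjusted p = 9.9e-07, and adjusted p = 0.24 with an estimated correlation), led by Dlst (2.05-fold lower) and Dlat (1.92-fold lower). Of 33 complex I subunit genes, 30 fell (33 adjusted over the list alone, median -0.64, adjusted p = 3.5e-08, and adjusted p = 0.33 with an estimated correlation), with Ndufs1 1.9-fold and Ndufa4 1.79-fold lower. Of 30 genes of complexes III and IV and ATP synthase, 24 fell (29 adjusted over the list alone, median -0.56, adjusted p = 4.3e-07, and adjusted p = 0.39 with an estimated correlation), with Uqcr11 1.89-fold and Cox8b 1.81-fold lower.

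In the list of energy metabolism regulators, 10 of 19 genes fell (10 adjusted over the list alone, median -0.51, adjusted p = 0.0081, and adjusted p = 0.26 with an estimated correlation). The list also holds the creatine kinase genes Ckm and Ckmt2 and the carrier gene Slc25a4, which are not regulators. They were among the genes that fell (-0.89, -0.51 and -0.44). Ppara, a nuclear receptor that drives fatty acid oxidation genes, was 2.56-fold lower and the coactivator gene Ppargc1b 2.32-fold lower. The related coactivator gene Ppargc1a stood at -0.54 ± 0.21 (adjusted p = 0.13), with other probe sets at -0.71 (adjusted p = 0.011) and -0.57 (adjusted p = 0.17). Glycolysis genes went both ways, with 5 higher and 9 lower among 23 (6 and 14 adjusted over the list alone, median -0.5, camera adjusted p = 0.41, and fry lower with adjusted p = 0.0054). The lactate exporter gene Slc16a3 was at least 3.53-fold higher, although its adjusted p was 0.069 on that scale, and the regulatory kinase gene Pfkfb3 4.44-fold higher. Pfkfb1 was 2.73-fold lower. In pairs chosen after their values were seen, the glucose transporter gene Slc2a1 was 2.46-fold higher and Slc2a4, the insulin-responsive form, 2.51-fold lower. Likewise Pfkp was 2.59-fold higher and Pfkm, the muscle form of the same enzyme, 2.08-fold lower.

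Sarcomere genes fell in 11 of 20 cases and none rose (17 fell adjusted over the list alone, median -0.53, adjusted p = 0.00069, and adjusted p = 0.25 with an estimated correlation). Nebl was 2.07-fold lower (adjusted p = 0.063 with signals under 64 set to 64), Ldb3 1.77-fold lower and the cardiac troponin gene Tnni3 1.45-fold lower (-0.54 ± 0.13, adjusted p = 0.037). The cardiac myosin heavy chain gene Myh6 stood at -0.46 ± 0.13 (adjusted p = 0.062). Quantile normalization ended the list's call (median -0.16, adjusted p = 0.099) and that of Tnni3 (-0.10, adjusted p = 0.51). The atrial myosin light chain genes Myl4 and Myl7 belong to this list and, as described with the atrial markers, were far below control level on infected replicates 1 and 3. On infected replicate 2 their log2 signals of 12.57 and 12.48 lay just under the lowest controls (12.76 and 12.78). A second probe set of Myl4 fell (-1.58, adjusted p = 0.04). Per array, energy metabolism minus sarcomere mean log2 signal was 0.21 ± 0.40 (SD, n = 3) in infected and -0.05 ± 0.03 (SD, n = 3) in control hearts, a difference of 0.26 (two-sided exact permutation p = 0.4, smallest possible 0.1). With 1 array left out at a time the difference ran from 0.14 to 0.49, and with medians in place of means it was -0.06. Without Myl4 and Myl7, a choice made after seeing the data, the difference was -0.16 (exact p = 0.1).

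Calcium handling and ion channel genes fell in 14 of 22 cases (18 adjusted over the list alone, median -0.86, adjusted p = 4.7e-05, and adjusted p = 0.14 with an estimated correlation). Kcnip2, an accessory subunit of the transient outward potassium channel, was 4.08-fold lower (a second probe set stood at -1.11, adjusted p = 0.13), Kcnj11 2.79-fold lower and Kcnj3, a channel gene abundant in atria, 2.56-fold lower. The calcium pump gene Atp2a2 stood at -0.45 ± 0.13 (adjusted p = 0.065) and at 0.01 after quantile normalization, while 3 other probe sets of the gene fell (-0.54, -0.62 and -1.23, adjusted p = 0.023, 0.021 and 0.0066). Junction genes fell in 5 of 10 cases (6 adjusted over the list alone, median -0.54, adjusted p = 0.013, and adjusted p = 0.2 with an estimated correlation), led by Dsc2 (2.2-fold lower) and Tjp1 (1.7-fold lower).

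Genes of the cardiac stress program went both ways. Of 13 named genes, 2 rose and 4 fell (2 and 9 adjusted over the list alone, median -0.73, camera adjusted p = 0.2, and fry lower with adjusted p = 0.00076). The stress cytokine gene Gdf15 was 3.5-fold higher and skeletal actin, Acta1, 2.54-fold lower. The natriuretic peptide gene Nppb was bright in both groups (9504 against 10047, -0.08 ± 0.12, adjusted p = 0.65; 0.14 after quantile normalization). Nppa, which atria express most strongly, stood at -1.61 ± 0.53 (adjusted p = 0.084) and, like the atrial markers, was highest among infected hearts on replicate 2.

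Matrix genes rose in 8 of 31 cases and 1 fell (11 and 4 adjusted over the list alone, median 0.23, adjusted p = 0.024, and adjusted p = 0.15 with an estimated correlation). Timp1, an inhibitor of matrix proteases, was 9.97-fold higher, tenascin C, Tnc, at least 4.64-fold higher, and Lum 2.19-fold lower (adjusted p = 0.078 with signals under 64 set to 64). Col3a1 was 2.52-fold higher (1.33 ± 0.16, adjusted p = 0.0056). The list's call ended when only probe sets above the median brightness were kept (adjusted p = 0.059) and when a gene's probe sets were averaged (adjusted p = 0.062). Fibroblast markers split, with 4 higher and 6 lower among 15 (5 and 7 adjusted over the list alone, median -0.25, camera adjusted p = 0.9, and fry of opposite sign with adjusted p = 0.71). Thy1, which T cells also express, was 7.59-fold higher and Mgp 2.96-fold lower.

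Endothelial markers went both ways. Of 24 named ones, 3 rose and 5 fell (4 and 8 adjusted over the list alone, median -0.29, camera adjusted p = 0.52, and fry lower with adjusted p = 0.04). The adhesion molecule genes Selp and Vcam1 were at least 4.02-fold and 4.79-fold higher, and the water channel gene Aqp1 was 5.28-fold lower. Smooth muscle and pericyte markers fell in 6 of 15 cases and none rose (6 fell adjusted over the list alone, median -0.93, adjusted p = 0.012, and adjusted p = 0.2 with an estimated correlation), led by smooth muscle actin, Acta2 (4.65-fold lower, with a second probe set at -0.98, adjusted p = 0.43), and Myh11 (2.79-fold lower). The call of Myh11 ended under quantile normalization (adjusted p = 0.055) and with signals under 64 set to 64 (adjusted p = 0.073).

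Atrial markers differed among the infected hearts themselves. Sln, Myl4 and Myl7, chosen after their values were seen, had a mean log2 signal of 12.47, 12.46 and 13.5 in the controls, of 12.14 on infected replicate 2 and of 4.91 and 4.83 on infected replicates 1 and 3. Over the 11 named atrial markers, 2 fell (1 adjusted over the list alone, median -1.75, adjusted p = 0.044, and adjusted p = 0.57 with an estimated correlation), led by Stard10 (3.37-fold lower, adjusted p = 0.078 with signals under 64 set to 64), and fry gave a lower direction with adjusted p = 0.053. On infected replicate 2, 5 of the 8 markers other than Sln, Myl4 and Myl7 lay below every control. The list's camera call ended under quantile normalization (adjusted p = 0.083), with arrays centred on ribosomal protein genes (0.067), without probe sets whose IDs end in _x_at or _s_at (0.062), with signals under 64 set to 64 (0.058) and without infected replicate 1, infected replicate 3 or control replicate 3 (adjusted p = 0.11, 0.085 and 0.091). It also ended with the mean of Sln, Myl4 and Myl7 as a covariate (0.77) and with infected replicate 2 alone (0.27), but the first is built from members of the list and the second is 1 array, so neither bears on the call. With infected replicate 2 alone against the 3 controls, a comparison chosen after seeing the data, limma called 0 probe sets at an adjusted p under 0.05, while 6296 had an unadjusted p under 0.05.

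Adipocyte markers fell in 7 of 12 cases (11 adjusted over the list alone, median -3.39, adjusted p = 0.0066, and adjusted p = 0.42 with an estimated correlation). Their mean log2 signal per array was 5.61 ± 0.27 (SD, n = 3) in infected hearts and 8.96 ± 1.24 (SD, n = 3) in controls, where control replicate 3 stood at 10.39 and the other two at 8.29 and 8.19. The sources used here do not say whether fat around the heart was trimmed alike in both groups. Car3, Scd1, Pck1 and Cidec, named above among the lowest log2 fold changes that passed, are also genes that fat cells express strongly.

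Clock genes of the Per and Dbp group fell together. Of 9 named clock genes, 6 fell (1 rose and 6 fell adjusted over the list alone, median -1.68, adjusted p = 0.024, and adjusted p = 0.24 with an estimated correlation). Per2 was at least 6.32-fold lower, Dbp 4.43-fold lower and Tef 3.45-fold lower. Clock, chosen after its value was seen, stood at 0.06 ± 0.18 (adjusted p = 0.84). Among probe sets above the median brightness the list's adjusted p was 0.052.

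The authors' deposited table was set beside these results. Of 1202 probe sets other than controls in its list of genes at least 2-fold higher, 1143 rose here (95.1%), and of 266 in its list of lower ones 227 fell (85.3%). Conversely, 453 probe sets at least 2-fold higher here and 639 at least 2-fold lower here are not in those lists. In the authors' deposited table Gbp6 was 76.5-fold, Ccl5 64.9-fold and Gzmb 57.4-fold higher (at least 98.8-fold here), and Car3 43.2-fold and Adipoq 19.9-fold lower. The authors' deposited table also lists Myl4 as 21.5-fold, Myl7 as 20.9-fold and Sln as 16.6-fold lower, the genes that differed among the infected hearts. Across 12320 probe sets in the authors' deposited table, which describe the same hearts and are not independent, log2 fold changes correlated with those here with r = 0.89, and 92.6% had the same sign. By its title the authors' table was selected for significance in these same hearts, which raises both values. Over the probe sets of the 2 lists, the slope of the values here on those of the authors' deposited table was 1.18.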

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

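The floor at 64, the atrial score as a covariate, infected replicate 2 alone and the sarcomere list without Myl4 and Myl7 were chosen after the data were seen, and the other alternatives before the data were examined. Of 30 lists with a camera call, 23 kept it under every alternative except camera with an estimated correlation, which called 0 lists higher and 0 lower (lowest adjusted p 0.14), whereas fry called 20 higher and 16 lower. Of 939 list values under the alternatives, 880 kept their side of the threshold, 47 lost it, 12 gained it and 0 changed sign among calls. Of 140 named genes that changed, 57 did so under every alternative that measured them except infected replicate 2 alone. The 3 other scalings kept 40.1 to 46.6% of calls on the higher side, against 46.5%. With only probe sets above the median brightness, 918 rose and 454 fell by at least 2-fold, as fewer were tested. At an adjusted p under 0.01, 1085 probe sets rose and 581 fell, 998 and 347 of them by at least 2-fold, and 686 genes rose and 376 fell. With signals under 64 set to 64, 499 fell by at least 2-fold, since dim folds shrink. With the atrial score as a covariate, which takes a degree of freedom and partly follows infection, 764 probe sets rose and 387 fell (763 and 380 by at least 2-fold), 470 genes rose and 204 fell, and 613 and 77 members of the authors' higher and lower lists did. With infected replicate 2 alone every one of these counts was 0 by limma at an adjusted p under 0.05 (6296 at an unadjusted p under 0.05), and energy minus sarcomere was -0.2. It was -0.16 without Myl4 and Myl7. The move from 0.26 comes from the removal of 2 genes that differ among infected hearts, and the cause of the remaining -0.16 was not tested.

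The replicate numbers gave no sign of pairing, as deviations of same-numbered arrays correlated at -0.034, -0.052 and -0.138, and no array correlated best with its own number. With the number as a replicate block, 1078 probe sets rose and 543 fell, 456 of them by at least 2-fold, 639 genes rose and 292 fell, and 145 members of the authors' lower list fell. Leaving out 1 array at a time gave 1465 to 1852 higher and 1219 to 1890 lower probe sets, and 860 to 1096 higher and 717 to 1074 lower genes, with fewer arrays in each fit. The lowest values came without infected replicate 3 for the higher counts and without control replicate 3 for the lower counts. Depth of signal limits the dim probe sets most, since 7270 have a mean signal under 64.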

Other observations

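The choice of genes said to have been selected after their values were seen, the test of atrial genes against the lowest control, the test of ion channel against sarcomere genes and the sarcomere value without Myl4 and Myl7 were settled only after the results were known. Mast cell and eosinophil markers went both ways, with 1 higher and 3 lower among 7 (1 and 4 adjusted over the list alone, median -0.99, or 0.0 with signals under 64 set to 64, camera adjusted p = 0.5). Hdc, the histamine-forming enzyme gene that other myeloid cells also express, was at least 4.73-fold higher (limma adjusted p = 0.0044 with signals under 64 set to 64). The mast cell protease gene Tpsb2 fell from a mean signal of 41.7 to 5.23, a range where both values are dim, and the call ended with signals under 64 set to 64 (adjusted p = 0.31). Antioxidant genes also split, with 8 higher and 9 lower among 29 (9 and 10 adjusted over the list alone, camera adjusted p = 0.82). Their median was 0.01 in the main setting and between -0.05 and -0.01 under the 3 other scalings, their mean was 0.11, and fry gave a lower direction with adjusted p = 0.58. Heme oxygenase, Hmox1, was 5.73-fold higher, thioredoxin, Txn1, 2.74-fold higher and Gpx1 2.56-fold higher, whereas Gstm1, chosen after its value was seen, was 2.52-fold lower.

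Glucocorticoid-responsive genes rose in 3 and fell in 2 of 9 cases (4 and 2 adjusted over the list alone, median 0.64, camera adjusted p = 0.33), with Lcn2 higher and the phosphatase gene Dusp1 2.36-fold lower. Immediate-early genes rose in 5 of 13 cases and 1, Dusp1, fell (5 and 1 adjusted over the list alone, median 0.58, camera adjusted p = 0.026, and adjusted p = 0.23 with an estimated correlation), led by Klf6 (2.54-fold) and Myc (2.41-fold). That call ended among probe sets above the median brightness (adjusted p = 0.11). Skeletal muscle markers fell in 3 of 8 cases (4 adjusted over the list alone, median -0.66, or -0.2 with signals under 64 set to 64, camera adjusted p = 0.12, and fry lower with adjusted p = 0.002), led by Tnni2 (at least 1.73-fold lower, from a mean signal of 111 to 14.9, with an adjusted p of 0.055 once signals under 64 were set to 64). Camera called that list with the atrial score as a covariate (adjusted p = 0.039) and with infected replicate 2 alone (adjusted p = 0.034), where the controls supply all of the spread. Ribosomal protein genes rose in 1 of 31 cases, Rpl12 at 1.52-fold, with an adjusted p of 0.051 where arrays were centred on their median (0 adjusted over the list alone, median 0.06, camera adjusted p = 0.27), and as a list under quantile normalization (median 0.24, adjusted p = 0.00039). Neither of the 2 named erythroid markers changed (0 adjusted over the list alone). None of 5 thymus, lung and airway markers changed (0 adjusted over the list alone, camera adjusted p = 0.44, and fry lower with adjusted p = 0.017), with Epcam at -1.26 ± 0.77 (adjusted p = 0.29) and means of 4.33 and 10.4. The sex-linked list had 0 named members.

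Further metabolic genes were chosen after their values were seen. Cdo1 was at least 10.5-fold lower and Cyp2e1 11.2-fold lower, and the brown fat gene Ucp1 stood at -5.69 ± 2.11 (adjusted p = 0.11). No explanation was tested for the fall of these genes, of adipocyte markers or of Cd163, which fell from 205 to 2.04 while the mean log2 signal of monocyte and macrophage markers stood at 10.74 ± 0.24 (SD, n = 3) in infected and 7.53 ± 0.43 (SD, n = 3) in control hearts.

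The first pattern weighed is the number of probe sets that changed. The real grouping called 5167 probe sets and the highest of the other groupings 0, so that 1 of the 10 splits was as large. This count cannot decide about chance. The 10 splits are too few for a share under 0.05, and the other groupings mix infected and control arrays, which widens their spread. The limma adjusted p values are the test of each probe set against chance. A difference in RNA quality is argued against, since the 3'-minus-5' log2 signal of the Gapdh control probe sets differed by 0.03 between groups (SD 0.06) and that of Actb by -0.03. A different time of day at collection may add to it and stays open: genes of the Dbp phase averaged -1.89, the opposite phase averaged -0.43 over Npas2 and Clock, Npas2 is dim, and Arntl and Nr1d1 are not named here. Infection is the difference the design names, and no test here parts it from an unrecorded difference between the groups.

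The second pattern is the lower signal of heart muscle genes. Missing atrial tissue in infected hearts 1 and 3 is argued against as its cause for the energy genes, because their mean on infected replicate 2, the infected array with the highest signals of Sln, Myl4 and Myl7, lay -0.74 log2 units from the lowest control (control SD 0.04) and was the lowest of the infected arrays (12.4, against 12.61 and 12.56). Dilution of muscle RNA by infiltrating cells could lower all muscle genes alike. For the energy genes it cannot be told apart from lower expression. Energy minus sarcomere differed by 0.26 with an SD of 0.4 among infected arrays. Without Myl4 and Myl7 it differed by -0.16 (SD 0.04 in infected and 0.05 in control hearts, exact permutation p = 0.1, the smallest possible). The sign thus turns on a choice made after the data were seen. As the whole change of the ion channel genes, dilution cannot be told apart either. Ion channel minus sarcomere signal differed by -0.35 (SD 0.12, exact permutation p = 0.1, the smallest possible) without Myl4 and Myl7. With the full sarcomere list it differed by 0.07 (SD 0.26), so the result turns on a choice made after the data were seen. The full-list value was -3.04 and -3.11 on infected replicates 1 and 3, where Myl4 and Myl7 were far below control level. On infected replicate 2 it was -3.52, below the controls (-3.24 to -3.37), but this is 1 array. Lower expression within muscle cells of infected hearts remains open as a hypothesis.

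The third pattern is the low signal of atrial genes. A candidate explanation is that atrial tissue was sampled from infected heart 2 and not from infected hearts 1 and 3. Over the 9 atrial markers other than Myl4 and Myl7, the median of infected replicate 2 minus the mean of infected replicates 1 and 3 was 1.6 log2 units (SD 2.82). Sln, 1 of the 9, stood at 9.46 and had been chosen after its value was seen. Of the 9, 8 with Sln among them were higher on infected replicate 2 than on infected replicates 1 and 3, as were 32.2% of all probe sets. Lower expression in every infected heart cannot be told apart from it: over the 8 markers other than Sln, Myl4 and Myl7, which were picked for their values, infected replicate 2 minus the lowest control had a median of -0.31 log2 units (SD 1.44), 5 of the 8 lay below every control, and the comparison rests on 1 array. Loss of atrial gene expression in 2 of the 3 infected hearts was not tested and stays open.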
